A study of Homo sapiens with 4 samples.

How the data were processed

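Gene expression was measured in AGS cells, an established human gastric adenocarcinoma line, on 4 Affymetrix arrays. RNA was harvested 8 h after the medium was replaced by fresh medium or by medium with 10 µg/ml Helicobacter pylori lipopolysaccharide (LPS, the outer-membrane glycolipid of the bacterium). Each group held 2 arrays, and the series' design text speaks of 2 independent experiments. Per the labels' protocols, biotin-labelled cRNA was made from total RNA by in vitro transcription and hybridised to a single-channel array.

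The deposited table held log2 expression values for 54675 probe sets on each array. The submitters' processing notes name MAS5 and RMA, without their roles or versions. The values themselves had the form of RMA output: log2 scale, no zeros, minima of 3.19 to 3.28 and medians of 6.31 to 6.36 on all arrays. Background and normalization settings were not given in the sources used here. RMA compresses differences of dim probe sets, so that folds of weakly expressed genes are likely to be understated. Detection calls were not used here, and a dim gene may be background rather than transcript. The number of arrays limits the precision.

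The deposited log2 values were used without further normalization between arrays. Probe sets were named through a platform annotation, with symbols checked through the gene number against a current gene table. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. The gene number was found in the current table for 41043 of the first, no symbol needed updating, and 54 kept the annotation's symbol. The 62 control probe sets and those with no or several symbols were left out of the gene tests. The probe set with the highest mean over all 4 arrays stood for each gene, which gave 19775 genes, of which 10523 had more than 1 probe set. Probe sets ending in _x_at or _s_at can share signal between related genes. Every data column of the table was used.

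LPS-treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All p-values given for single genes come from that moderated test. Confidence intervals are 95% intervals of the same fit, and values per group are log2 means ± SD over 2 arrays. A second count needed no test: genes whose group means differed by at least 2-fold and whose treated arrays both lay on one side of both untreated arrays. The same rule was applied to the other 2 ways of splitting the 4 arrays. With 2 arrays against 2, an exact permutation test of 1 gene cannot give a p under 0.33.

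Before the data were examined, 30 gene lists were fixed for gastric epithelial cells, a bacterial product and other cell types that a culture could hold. Each was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and adjusted over the lists. The calls were repeated with an estimated correlation and with fry. The call with an estimated correlation also gave larger p-values where the estimate was 0 or below. Failing it therefore does not by itself show correlation among members. The rule for named genes was fixed at the same time: up to 12 genes in each direction past the threshold, filled to 8 by the smallest unadjusted p where fewer passed (arrays not overlapping, brighter group at or above its median over genes), up to 4 members of each list by the size of the moderated statistic, and 16 genes of the LPS response whatever their values. Genes outside that rule are said to have been chosen after their values were seen. The alternatives were quantile normalization, a filter at median expression, the mean of all probe sets of a gene, no _x_at or _s_at probe sets, no intensity trend, a replicate block, every probe set as its own test, other fold minimums, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.

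The test was tried on simulated data: 20 sets of 4 arrays with the real genes' means, variances drawn from the fitted distribution, and 200 of 19775 genes changed. For the comparison of LPS with untreated arrays, 23.7% of genes changed 1.5-fold passed the adjusted test, 88.5% of those changed 2-fold and 99.5% of those changed 3-fold. With fewer genes truly changed, the adjustment is stricter than in that simulation. A list of 15 genes shifted by 0.3 on the log2 scale passed an unadjusted p of 0.05 in 20 of 20 sets, and an unshifted one in 0. The simulated genes varied independently and without a replicate effect. These rates therefore do not carry over to lists with correlated members, and the estimated correlation was 0.24 for antimicrobial proteins and 0.5 for metallothioneins.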

Results

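The data comprised 4 arrays of AGS gastric epithelial cells: 2 of untreated cells and 2 of cells exposed for 8 h to 10 µg/ml H. pylori LPS. The comparison asks which transcripts of a gastric epithelial line differ after exposure to purified LPS without live bacteria. Correlations between arrays across genes, which are not independent replicates, ran from 0.996 to 0.9979. The SD of the gene-wise difference was 0.169 between the untreated arrays and 0.217 between the treated arrays, and it ran from 0.154 to 0.217 between a treated and an untreated array. The spread within a group was as large as that between groups.

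CYP1A1 had the largest difference of the genes tested. It encodes a cytochrome P450 that metabolises polycyclic aromatic compounds and is a known target of the aryl hydrocarbon receptor. Its log2 expression was 8.57 ± 0.18 (SD, n = 2) in untreated and 9.78 ± 0.03 (SD, n = 2) in LPS-treated cells, 2.32-fold higher with a 95% interval of 1.90 to 2.83. The difference was 1.11 on the log2 scale between the arrays numbered 1 and 1.32 between those numbered 2. It did not pass the adjusted test (limma, adjusted p = 0.299), and 1 probe set measured the gene. Over 10 alternative settings the adjusted p ran from 0.0085 to 1, and it passed only without LPS replicate 2 (0.0085).

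With limma, 0 of the 19775 genes tested passed the adjusted threshold in either direction (smallest adjusted p = 0.299). Without LPS replicate 2, 2 genes were called higher and 14 lower, and without each of the other arrays 0. At an unadjusted p under 0.05 there were 559 genes, 249 higher and 310 lower with LPS. Chance alone would give 989 if nothing else separated the arrays. The same count was 3069 in the split by replicate number and 193 in the crossed split, so 989 is no firm reference. With the replicate number as a block, the comparison of LPS with untreated arrays gave 1487, above the chance value, and 0 passed the adjusted threshold. The median 95% interval reached 0.27 on the log2 scale, or 1.21-fold, to either side of the estimate. CYP1A1 was the only gene at least 2-fold apart without overlap of the arrays, and 0 genes were lower by that rule. The same rule gave 4 genes when the arrays were split by replicate number and 0 in the crossed split. At a 1.5-fold minimum, 1 gene was higher and 9 were lower with LPS, against 66 genes by replicate number and 4 in the crossed split. Over all genes, 29.6% had no overlap between treated and untreated arrays, where chance gives 33.3% if the 4 arrays are exchangeable. Same-numbered arrays deviated together, so 33.3% is no exact reference here.

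None of the 8 lower genes with the smallest p-values under the naming rule passed the adjusted test (limma, adjusted p = 1 for each). SEMA3C, a secreted semaphorin, had 7.82 ± 0.01 in untreated and 7.14 ± 0.02 in treated cells (SD, n = 2), a difference of -0.68 ± 0.11 (SE). DKK1, a secreted Wnt inhibitor and one of the brightest genes of the group, had 12.77 ± 0.01 against 12.33 ± 0.05, a difference of -0.45 ± 0.08. THBS1, the matrix glycoprotein thrombospondin 1, differed by -0.62 ± 0.11, and its other probe sets differed by -0.36 to 0.15. Without _x_at and _s_at probe sets its difference turned to 0.15. The receptor tyrosine kinase-like gene ROR1 differed by -0.75 ± 0.14 on its brightest probe set and by -0.06 on each of its other probe sets. The growth factor receptor gene PDGFRA differed by -0.55 ± 0.13, the glycosyltransferase gene B3GNT2 by -0.39 ± 0.09, RP2 by -0.57 ± 0.13 and the kinetochore gene CENPQ by -0.62 ± 0.15. On other probe sets, B3GNT2 differed by -0.13 and -0.06, PDGFRA by 0.01, 0.07 and 0.08, RP2 by 0.00 and SEMA3C by -0.08. The other genes at least 1.5-fold lower without overlap of the arrays, chosen after their values were seen, were TSPAN2 (-0.77), KAT2B (-0.66), NOCT (-0.65), RTKN2 (-0.61) and PSENEN (-0.59). PSENEN differed by -0.05 between the arrays numbered 2. RTKN2 was at 7.71 and 7.50 in untreated cells, 7.34 on LPS replicate 1 and 6.66 on LPS replicate 2. KAT2B was at 7.96 and 7.66, then 7.39 and 6.91, in the same order. NOCT was at 7.54 on untreated replicate 1 and 6.94 on untreated replicate 2, against 6.53 and 6.65 in treated cells. CLIC3 (-0.71) and CKS2 (-0.66), also chosen afterwards, were past that fold with arrays that overlapped.

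The higher genes ranked after CYP1A1 by the same rule differed by 1.25-fold to 1.39-fold, and none passed the adjusted test (limma, adjusted p = 1 for each). FGF9, a fibroblast growth factor, was at 7.54 ± 0.10 in untreated and 8.02 ± 0.22 in treated cells (SD, n = 2), 1.39-fold, and its dimmer probe set differed by -0.10. SOS1, which activates Ras, was 1.31-fold higher, and its 4 brightest probe sets differed by 0.32 to 0.39 on the log2 scale and its dimmest by -0.14. The MHC class I gene HLA-B was 1.29-fold higher, with differences of 0.23 to 0.36 over its 3 probe sets, which can share signal with related HLA genes. NDRG1 was 1.27-fold higher, UPP1, a uridine phosphorylase, 1.25-fold and ANKS3 1.26-fold. RXYLT1 was 1.27-fold higher on its brightest probe set and differed by -0.54 on its other one.

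**Figure D1:**
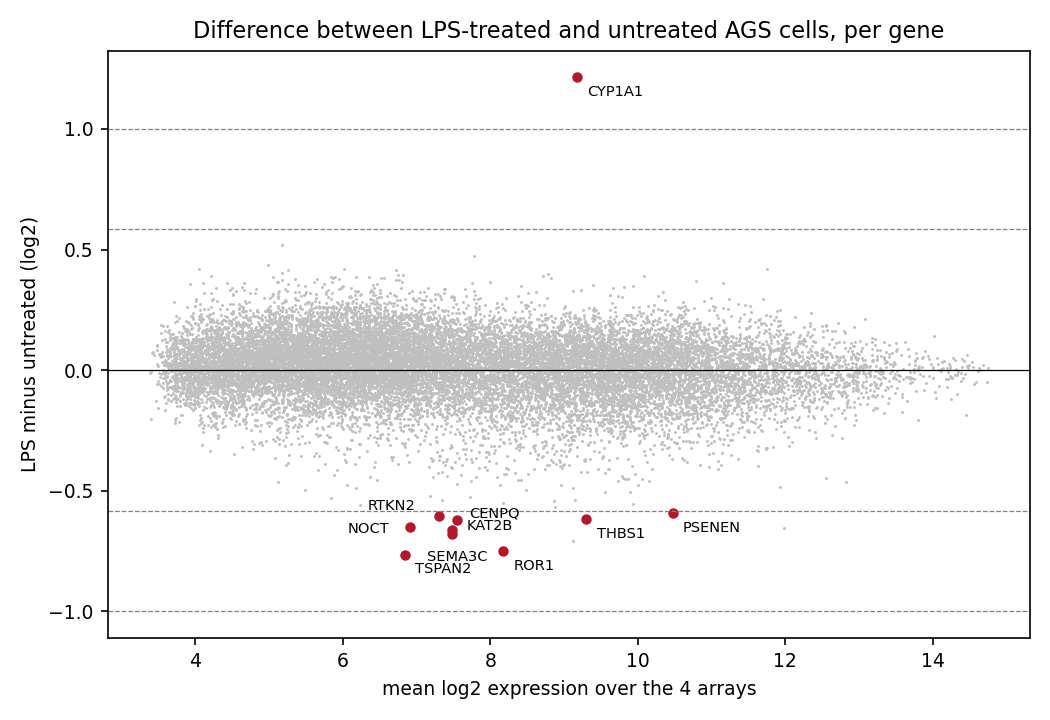
Each point is 1 of 19775 genes, with mean log2 expression over the 4 arrays on the x axis and the log2 difference of LPS-treated minus untreated means on the y axis; dashed lines mark 1.5-fold and 2-fold. Red points are the 10 genes at least 1.5-fold apart without overlap of the arrays: CYP1A1 lies at 1.21 and the other 9 lie between -0.59 and -0.77.

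The chemokine genes that NF-kB controls in epithelial cells did not pass the test as a list or singly, with 13 members measured. CXCL8, encoding interleukin 8, had 7.08 ± 0.13 in untreated and 6.83 ± 0.07 in treated cells (SD, n = 2), a ratio of 0.84 with a 95% interval of 0.69 to 1.03. The second, dimmer CXCL8 probe set differed by 0.32 in the opposite direction, so the probe sets disagree. The brighter one ends in _x_at and lay below the median over genes of 7.24 in untreated cells. Its interval may therefore not bound a change in the transcript. The treated to untreated ratio was 0.99 for CXCL1 (interval 0.80 to 1.22), 1.02 for CXCL2 (0.82 to 1.27), 0.87 for CXCL3 (0.68 to 1.11) and 1.01 for CCL20 (0.86 to 1.17). CCL20 was dim at 4.96 and 4.97, below the median over genes of 7.24 in untreated cells. CXCL11, an interferon-inducible member, differed by -0.33 at an unadjusted p of 0.0238. The list had a median of -0.03 and an adjusted p of 0.17 (camera).

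Other genes of the LPS response did not pass either. The NF-kB inhibitor gene NFKBIA had a ratio of 1.12 (interval 0.91 to 1.37), with a difference of 0.34 in the arrays numbered 1 and -0.02 in those numbered 2. The ratio was 0.98 for TNFAIP3 (0.82 to 1.18), 1.04 for IL6 (0.83 to 1.31), 1.11 for IL1B (0.91 to 1.36) and 0.94 for TNF (0.78 to 1.14). IL6, TNF, IL1B and TLR2 all lay below the median over genes in untreated cells, at 6.00, 6.32, 6.95 and 6.38. TLR4, the receptor of enterobacterial LPS, stood at 7.49 ± 0.18 and 7.23 ± 0.24 (SD, n = 2), a ratio of 0.83 (0.65 to 1.07), with log2 differences of -0.44 to -0.05 over the settings tried. The adaptor gene MYD88 was bright at 10.60 and 10.55, a ratio of 0.97 (0.83 to 1.13), and TLR2 had a ratio of 0.99 (0.83 to 1.19). Of the Tribbles pseudokinase genes, TRIB3 had 9.99 ± 0.10 against 9.97 ± 0.03 (SD, n = 2), a ratio of 0.98 (0.83 to 1.16). TRIB1 had a ratio of 0.95 (0.83 to 1.10) and TRIB2 of 1.02 (0.84 to 1.23). The upper interval bounds of CXCL1, CXCL2, CXCL3, CCL20, IL6, TNF and TRIB3 all lay below 1.5-fold. The dim CCL20, IL6 and TNF may be background, so their bounds do not limit a change in transcript.

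**Figure D2:**
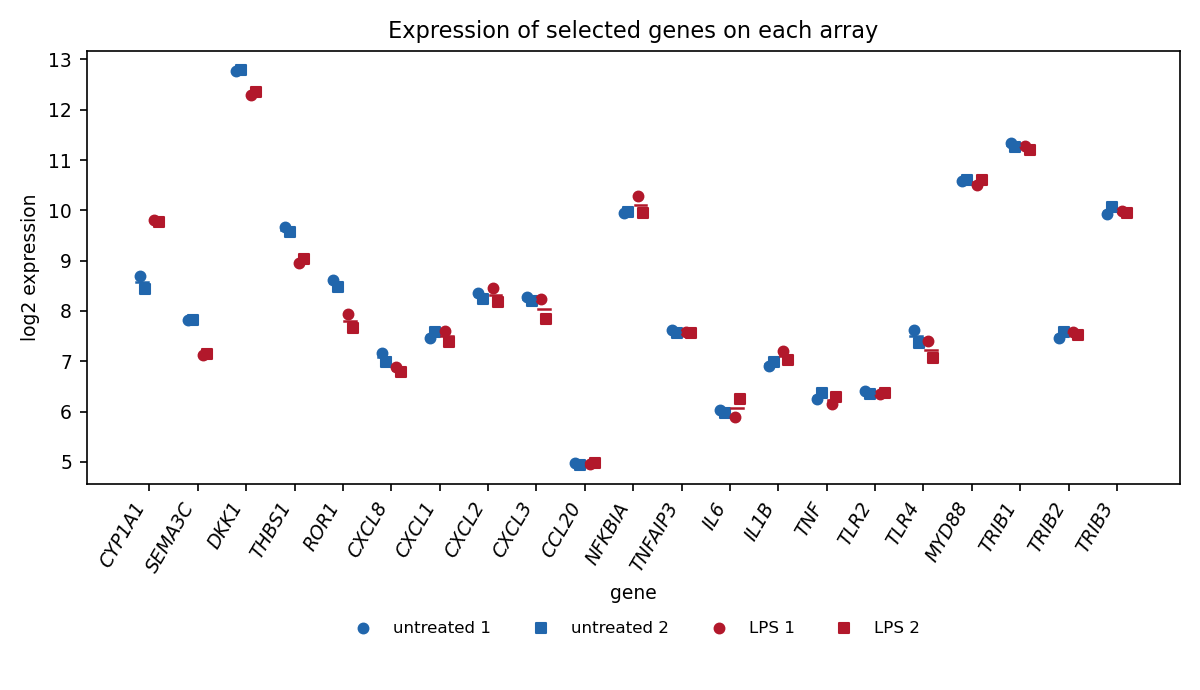
Log2 expression of 21 genes on each array: blue for untreated, red for LPS, circles for replicate 1 and squares for replicate 2, with short lines at the group means. CYP1A1 is higher and SEMA3C, DKK1, THBS1 and ROR1 are lower on both treated arrays. Of the chemokine, cytokine, receptor and Tribbles genes, CXCL8 is lower (-0.25) and IL1B higher (0.16) on both treated arrays. Treated and untreated arrays overlap for the rest, among them TLR4, which runs from 7.06 on LPS replicate 2 to 7.62 on untreated replicate 1.

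Of the 30 lists, 2 passed the camera test with the preset correlation. The TGF-beta responsive genes were lower as a list (adjusted p = 0.0044, median -0.15, 11 of 13 members below 0). That call was lost with an estimated correlation (adjusted p = 0.68), and no member passed over all genes or adjusted over the list alone. The estimate for this list was 0.04, and 0 of the 30 lists passed that way. For Wnt targets, with an estimate of -0.07, the unadjusted camera p still went from 0.025 to 0.14. The lost call therefore does not show correlation among members. SKIL, a SMAD co-repressor gene, differed by -0.33 ± 0.10 (SE), the matricellular gene CCN2 by -0.29 ± 0.12 and ID1 by -0.16 ± 0.09. PMEPA1, another TGF-beta target, went the other way by 0.34 ± 0.11. Other probe sets of SKIL differed by -0.53 to 0.11 and those of PMEPA1 by as little as -0.08. Over the settings tried SKIL ran from -0.45 to -0.13, CCN2 from -0.42 to -0.17, ID1 from -0.21 to -0.12 and PMEPA1 from 0.15 to 0.39. The list median was -0.08 between the arrays numbered 1 and -0.21 between those numbered 2. Over 14 alternatives the adjusted p ran from 0.000119 to 0.834, and the call also ended without LPS replicate 2 (0.379), without _x_at and _s_at probe sets (0.355) and with fry (0.533).

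The antimicrobial proteins were higher as a list (adjusted p = 0.043, median 0.12, 16 of 17 members above 0). With an estimated correlation, where 0 of the 30 lists passed, that call was lost as well (adjusted p = 0.68). No member passed over all genes or adjusted over the list alone. CAMP, encoding cathelicidin, differed by 0.28 ± 0.11 (SE), the siderophore-binding lipocalin gene LCN2 by 0.23 ± 0.11, the protease inhibitor gene SLPI by 0.21 ± 0.11 and S100A7 by 0.25 ± 0.12. Over the settings tried SLPI ran from 0.07 to 0.34, LCN2 from 0.11 to 0.34, S100A7 from 0.13 to 0.37 and CAMP from 0.21 to 0.34. LYZ, the lysozyme gene, differed by -0.15 ± 0.12 and ran from -0.28 to -0.02. Below median expression lay 12 of the 17 members, and dim genes as a whole were shifted by a median of 0.032 against 0.002 for the brighter ones. The list median was 0.08 between the arrays numbered 1 and 0.16 between those numbered 2. Over 14 alternatives the adjusted p ran from 0.039 to 0.834 and passed in 2. The call ended with quantile normalization (0.0863), the expression filter (0.308), the replicate number as a block (0.0535), fry (0.755) and no _x_at or _s_at probe sets (0.376), and without untreated replicate 1 (0.282), untreated replicate 2 (0.109) or LPS replicate 2 (0.338).

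None of the other 28 lists passed, and for 16 of them the sign of the median turned when 1 array was left out. Wnt targets came next (adjusted p = 0.16, median -0.04), and 2 of the 12 measured members, DKK1 and LGR5 (-0.39 ± 0.10, SE), passed when adjusted over the list alone but not over all genes. The 8 metallothionein-related genes had an adjusted p of 0.16 (camera) and a median of 0.13. MT2A was at 0.29 (0.16 to 0.42 over the settings tried) and MT1X at 0.20 (0.06 to 0.35). The median of the metallothionein list was -0.036 without _x_at and _s_at probe sets, 0.06 without LPS replicate 2 and 0.209 without LPS replicate 1. MHC class I presentation had 0.17 and 0.09: HLA-B and HLA-F lay above 0 at 0.36 and 0.32, and the peptidase gene ERAP1 below at -0.44. ERAP1 differed by -0.82 between the arrays numbered 1 and -0.07 between those numbered 2, and by -0.04 without _x_at and _s_at probe sets. Without _x_at and _s_at probe sets HLA-F was at -0.09 and the list median at 0.025, and without untreated replicate 1 the median was 0.014. Cholesterol synthesis genes had an adjusted p of 0.16 and a median of -0.04, with DHCR7 at -0.31 (-0.57 to -0.06 over the settings tried) and INSIG1 at -0.26 (-0.39 to -0.13). Epithelial junction genes had 0.17 and -0.03 and glycolysis 0.17 and -0.04. ER chaperones had 0.20 and 0.07, and immediate-early and MAPK feedback genes 0.20 and -0.04, with SPRY2 at -0.30. Interferon-stimulated genes had 0.25 and -0.02, with IFIT3 at -0.48. IFIT3 differed by 0.15 on its other probe set and by -0.74 and -0.22 within the same-numbered pairs.

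Apart from the markers of other cells, the remaining lists had adjusted p-values of 0.33 or more. The NF-kB feedback and survival targets had a median of 0.06 over 22 genes, with NFKBIZ at 0.28 and SOD2 at -0.37. NFKBIZ was at 0.03 without LPS replicate 1, and SOD2 at -0.02 without LPS replicate 2 and -0.08 without untreated replicate 1. Inflammatory cytokines and mediators had a median of 0.004, a mean of -0.015 and a test pointing down. The median was -0.122 without LPS replicate 2 and 0.073 without LPS replicate 1. Its member with the largest test statistic was PTGS2, the inducible prostaglandin synthase, at -0.40 ± 0.11 (SE). The TLR and NOD pathway genes had a median of -0.006 and an adjusted p of 0.44. The ATF4 amino acid stress response, to which TRIB3 belongs, had a median of -0.011, a mean of 0.027 and an adjusted p of 0.77 over 30 genes. Proteases and the plasminogen system (0.026, with MMP9 at 0.30 and PLAU at 0.26, or 0.10 to 0.41 over settings), EGF receptor and ligands (0.061), BCL2 family genes (-0.06), G2/M genes (-0.027) and ribosomal protein genes (-0.007) did not pass. Neither did p53 targets (0.006), heat shock genes (0.004), or gastric mucins and trefoil factors (0.098, with SOX2 at -0.41, or -0.57 to -0.17 over settings, and MUC5AC at 0.26). G1/S replication genes (0.001), NRF2 genes (0.008) and hypoxia genes (0.01) had medians just above 0 with tests pointing down.

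Markers of other cells lay mostly below median expression and did not pass. Leukocyte markers had a median of -0.043 (adjusted p = 0.17), with 13 of 15 measured members below median expression. Fibroblast and endothelial markers had a median of 0.072 (adjusted p = 0.20), with 11 of 15 members below median expression, and red cell markers 0.072 (adjusted p = 0.44). Without LPS replicate 2 the medians were -0.136, 0.005 and 0.041, and without LPS replicate 1 they were 0.012, 0.088 and 0.18.

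**Figure D3:**
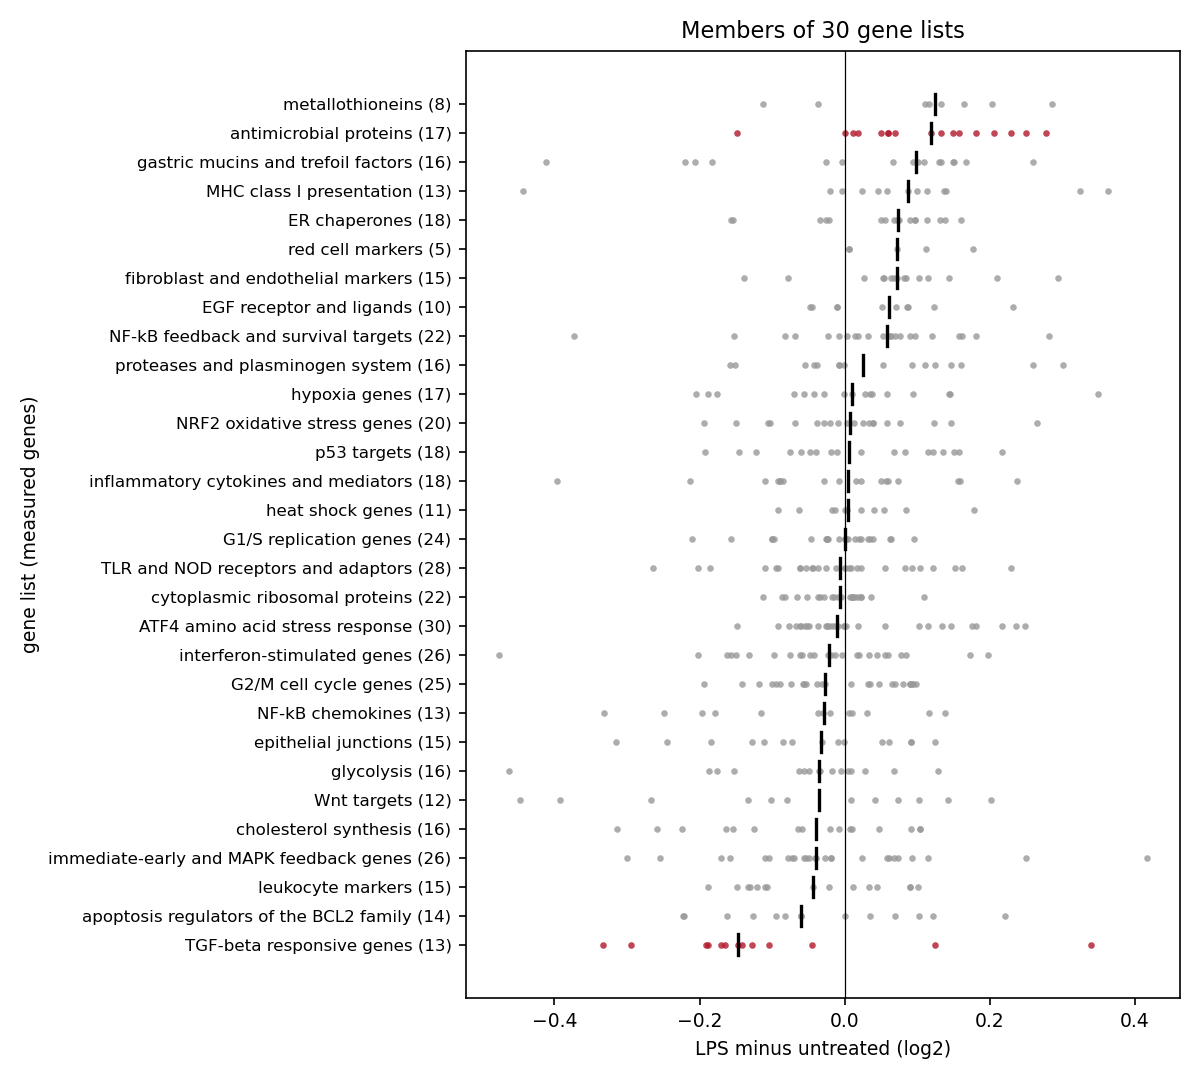
Each dot is a measured member of 1 of 30 gene lists (rows, with the number measured), placed by its log2 difference of LPS-treated minus untreated means; black bars are list medians and red dots mark the 2 lists that passed with the preset correlation. The TGF-beta list sits at a median of -0.15 and the antimicrobial list at 0.12, and no single dot passed over all genes.

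The arrays differed technically by replicate number. The poly-A control transcripts averaged 8.54 and 8.03 on the arrays numbered 1 (untreated and treated) and 7.53 and 7.48 on those numbered 2. The 18S ribosomal RNA control probe sets stood at 10.07 and 9.89 against 8.12 and 7.98. The hybridisation controls were highest on LPS replicate 1, at 10.57 against 9.68 to 9.88 on the other arrays. The log2 ratio of 3′ to 5′ control probe sets was 0.26 to 0.39 for GAPDH, and for ACTB it was 1.09, 0.94, 1.04 and 0.76 for untreated 1, untreated 2, LPS 1 and LPS 2. With the replicate number as a block, no gene passed either (limma, smallest adjusted p = 0.292). Of the 1487 genes at an unadjusted p under 0.05, 675 were higher and 812 lower, and 989 is no firm reference for that count either.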

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

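The count of genes past the adjusted threshold stayed at 0 in both directions under quantile normalization, the expression filter, the mean of probe sets, no _x_at or _s_at probe sets, no intensity trend, every probe set as its own test and the replicate block. Leaving out 1 array gave 0 to 2 higher and 0 to 14 lower genes. The calls came only without LPS replicate 2, where the lone treated array is assumed to vary like the untreated ones. The labels do not state that a replicate number marks a shared experiment. Same-numbered arrays deviated together (r = 0.44 across genes), and the first principal component, with 55% of the variance, separated the numbers, while the next, with 28.4%, separated treated from untreated arrays. Under the replicate block, the adjusted count was 0 and the number of genes 2-fold apart in the same direction in both pairs was 1 higher and 0 lower (chosen after seeing the data). The 2-fold count of lower genes ran from 0 to 6 with 1 array left out (2 without LPS replicate 1, 6 without LPS replicate 2). It was 9 at a 1.5-fold minimum, and at 3-fold the higher count was 0. Lists called higher numbered 0 under quantile normalization and under the replicate block, and 0 to 1 with 1 array left out. Lists called in either direction numbered 0 and 0 without _x_at and _s_at probe sets, with an estimated correlation, with fry, and with an estimated correlation together with the block, the expression filter or the loss of LPS replicate 2 (these 3 chosen after seeing the data). The cause was not tested. At median expression or above, the metallothioneins passed (adjusted p = 0.0278, with 0.0278 to 0.972 over their alternatives), and without LPS replicate 2 the glycolysis list did (adjusted p = 0.000314, with 0.000314 to 0.994 over its alternatives). With an estimated correlation in the same settings neither passed (camera, adjusted p = 0.742 for the metallothioneins), but no list passed that call in the main fit either. CYP1A1 ran from 2.13-fold to 2.53-fold over 10 alternatives. Of 1371 values of 144 named genes, 39 changed sign, and 0 of those 39 passed the adjusted threshold in their own setting. CXCL8 was 1.03-fold with the mean of its probe sets. A pseudocount was not run, the values being log2 already. The number of arrays sets the interval width, and dim genes have no detection call here.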

Other observations

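The tests of the second treated array, that of a single deviating array for CYP1A1, and the comparison of list percentiles with those of the other lists were chosen after the result was seen, and the patterns themselves were picked from these data. Split by replicate number, limma called 6 genes, all higher on the arrays numbered 1, at adjusted p of 0.05 or less. LINC02076 differed 2.96-fold, LOC100190986 2.37-fold, FOLR1, a folate receptor gene, 2-fold, the small nucleolar RNA gene SNORA21 1.92-fold, DCUN1D1 1.91-fold and the nuclear long noncoding RNA MALAT1 1.56-fold. FOLR1 stood at 12.14 and 12.03 on the arrays numbered 1 and at 11.10 and 11.07 on those numbered 2. Of the 310 genes lower with LPS at an unadjusted p under 0.05, 74.5% were higher on the arrays numbered 1, against 37.7% of all genes. Those genes were picked by p-value from the same arrays, the share among the 249 higher genes was not computed, and a cause was not tested. Among 13522 probe sets without a single gene symbol, 0 were 2-fold apart without overlap in either direction, and 4 were at least 1.5-fold lower with LPS.

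CYP1A1 had the only 2-fold difference, and a candidate explanation is activation of the aryl hydrocarbon receptor in treated cells. A single deviating array is argued against, since the fold was at least 2.13 with each array left out in turn. That restates array values already seen and is no independent test. The 7 other known targets were CYP1A2, CYP1B1, AHRR, TIPARP, ALDH3A1, NQO1 and UGT1A6. They were listed after CYP1A1's difference was seen but, NQO1 apart, before their own values were. NQO1 belongs to the preset NRF2 list, computed together with CYP1A1's difference. The targets had a median difference of 0.04, which is NQO1's own value. It lay at percentile 72.8 of 10000 random lists matched on expression, between the bounds set for and against the explanation. ALDH3A1 stood at 0.27, CYP1B1 at 0.26 and TIPARP at 0.12, while AHRR was at 0.00, UGT1A6 at -0.03 and CYP1A2 at -0.12. CYP1B1 was dim and its arrays overlapped, at 5.64 and 5.32 in untreated and 5.58 and 5.90 in treated cells. AHRR was dim as well, at 6.04 to 6.18, so both may be background. ALDH3A1 was at 8.18 and 8.58 in untreated and 8.59 and 8.71 in treated cells. Receptor activation stays open, and an effect of the gene's single probe set was not tested.

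Among 10000 lists matched on expression, the median of the TGF-beta list lay at percentile 0.02 and that of the antimicrobial list at 99.6. Such random lists ignore correlation among members, and 10 of the 30 lists lay below percentile 5 or above 95, where chance gives 3. Lists matched to the TGF-beta list had a median of 0.01 (5th to 95th percentile -0.055 to 0.077), so genes of like expression were not lower. No list that failed the camera test lay below 1.7. The TGF-beta list passed that test on these same differences, so the comparison with failed lists adds no separate evidence. Lists matched to the antimicrobial list had a median of 0.028 (5th to 95th percentile -0.026 to 0.084), so genes of like expression were shifted less than its 0.119. ER chaperones (99.9) and metallothioneins (99.8) failed the test and lay beyond the antimicrobial list. With 0 of 18 and 1 of 8 members below median expression, they show how loose such percentiles are, not a shift of dim genes. With percentiles that loose, a shift tied to expression level is not excluded for the antimicrobial list. Without LPS replicate 2 the antimicrobial median was 0.028, at percentile 86.0, so that this call may rest on 1 array. The TGF-beta median was then -0.121, at percentile 1.16 with lists that had failed the test as low as 0.4, and its adjusted p was 0.379, so that dependence on that array stays open, as does correlation among members.

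Without LPS replicate 2, 15 genes besides CYP1A1 passed, 14 of them lower, and these had no such difference on the second treated array. CKS2, a cell cycle gene, was at 12.39 and 12.25 in untreated cells, 11.03 on LPS replicate 1 and 12.29 on LPS replicate 2. A fault limited to single probe sets of LPS replicate 1, the array with the brightest hybridisation controls, is a candidate explanation. Other probe sets at or above the median of all probe sets were compared, 8 of them from 5 of these genes. Their median shift was 26.5% of that of the called ones, between the bounds set for and against it. The other ALDOA probe sets were also lower, by -0.84 and -1.01, but all ALDOA probe sets compared end in _x_at and may share signal. Those of PSMF1 lay at 0.07, -0.20 and 0.04, and those of ARPC4, DENND1A and ND4 at -0.30, -0.12 and -0.28. A response in the cells of LPS replicate 1 alone was not tested.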
